A study of Danio rerio with 30 samples.

How the data were processed

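Total RNA of whole AB wild-type zebrafish larvae was taken at 120 hpf with RNAzol, per the labels' protocols, and sequenced as RNA-seq. The labels name 10 groups of 3 libraries, an untreated control and 3 parabens at labels BMD5, BMD5/10 and BMD5/50, the divisors being 10 and 50. What BMD5 stands for in concentration is not given in the sources used here. Libraries took their group and replicate number from their titles, and the table's columns were matched to them by title, the columns named PP being those of propylparaben. Nothing in the labels says that the replicates were separate clutches, so p-values measure only the spread between these samples, which may be technical.

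The deposited table holds read counts per transcript and library, per the file headers, and these counts were used without change other than summing. The aligner, the counter, the genome build and the authors' test are not given in the sources used here. Per the file headers, the deposited table also gives log2 fold changes of each treated group against Control, with a p-value and a q-value for each. It also holds the authors' yes or no call, which a test on the values showed to be an unadjusted p under 0.05 with a log2 fold change of at least 1 in size. These columns were used only for the values credited to the authors' deposited table. The 60 columns of RPKM and TPM per library were not used. The table has 59876 transcripts of 32520 gene IDs and 31846 symbols, and 29201 of the gene IDs matched the gene name reference. Transcript counts were summed per symbol, which joined the gene IDs of 533 shared symbols, and reads of near-identical paralogs cannot be told apart at that step. No 2 libraries held identical counts (0 pairs). Total counts ran from 9711814 to 24468093 per library.

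Genes were tested with edgeR 4.0.16 (quasi-likelihood, limma 3.58.1) in R 4.3.3, with TMM scaling, filterByExpr at a minimum count of 10, all 30 libraries in 1 model of 10 group means and Benjamini-Hochberg adjustment within each comparison at 0.05. This left 18543 genes. There were 21 comparisons, 9 against Control, 9 between compounds at the same label and 3 between BMD5 and BMD5/50 of 1 compound. Standard errors of log2 fold changes come from the quasi-likelihood F statistic and intervals are 95%. Fitted fold changes compare means on the count scale, so libraries with higher counts of a gene weigh more, which for liver and pancreas genes are those numbered 2 and 3. An exact two-sided permutation test of 3 against 3 libraries cannot go below 0.1, so no such test was used for single values.

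Of 36 gene lists of tissue markers and pathways, 35 had at least 5 tested members and were tested with camera (limma) at a preset correlation between genes of 0.01, with an estimated correlation beside it, and with fry. The list not tested was that of estrogen response, with 4 of 17 members having enough reads. Camera compares a list with the other genes and fry asks whether its members move on balance in 1 direction. A list's score is the mean log2 CPM of its members in a library (prior count 2), and differences of scores have 95% intervals from a linear model with the same 10 groups. This model has no term for the replicate number, so the intervals include the spread between numbers and are wide where it is large. Scaling by RLE instead of TMM moved the median of all genes by at most 0.02 on the log2 scale and turned the direction of 0 of the 247 list medians called.

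The genes named in the report are 14 sentinel genes given for each BMD5 group, and by further parts of the rule the most changed genes with an adjusted p under 0.05 in each main comparison. As 0 genes passed, the further parts named none. Of the sentinels, 3 had too few reads to be tested: vtg1 with 19 reads over all libraries, cyp19a1b with 101 and tshba with 82. All other genes named were chosen after their values were seen, as the members of a list with the smallest p, those passing when adjusted over the list alone, or those that an alternative called. Adjustment over the list alone was made within each list and comparison and not across them, so some genes would pass by chance. The groups, the comparisons, the main test, the lists, the sentinel genes and the alternatives not marked as chosen later were fixed before the data were examined.

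The labels number the replicates 1 to 3 in each group. Deviations of same-numbered libraries from their group means were correlated across genes. In 14 of the 21 comparisons every such correlation was over 0.1, the rule by which the numbers were taken to pair the libraries. In the other 7 (EtP and PrP at BMD5, EtP at BMD5/10 and at BMD5/50 against Control, EtP against MtP at BMD5, PrP against EtP at BMD5/50, and the labels of PrP) at least 1 was not. For replicate 1 the correlations were 0.293 to 0.766. The pairing rests on the numbers and on these correlations, which cannot show it alone. Libraries numbered 2 and 3 both differed from those numbered 1, so they could correlate under this rule without being pairs. In PrP against EtP at BMD5/10, only 1 treated library correlated best with the reference library of its own number. The same held for EtP against MtP at BMD5/50.

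Alternatives were RLE scaling, no filter on low counts, DESeq2 1.42.0, a fit of only the 6 libraries compared, the replicate number as a block, each library left out in turn, and tests of transcripts in place of summed genes. After the data were seen, DESeq2 with the replicate block, fits of replicates 2 and 3 alone and leave-one-out tests of the lists were added. Fold changes shared between compounds were set beside 20 simulations of unchanged groups against the same controls.

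The tests were run on simulated counts for MtP BMD5 against Control in which 200 genes were changed and the replicate effect was kept (18355 genes). The simulated replicate effect was alike in all groups, and genes were drawn independently. In the data the replicate effect differed between groups, so the rates below may not hold for them. edgeR recovered 37.3% of genes changed 2-fold, 70.1% of those changed 4-fold and 86.4% of those changed 8-fold, and 2.99% of its calls were false. With the replicate block these were 50.7%, 83.6% and 95.5%, with 7.02% false, and DESeq2 with the block gave 55.2%, 83.6% and 93.9% with 13.4% false. On replicates 2 and 3 alone edgeR recovered 29.9%, 71.6% and 90.9%, with 3.70% false. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.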

Results

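RNA-seq libraries were made from total RNA of whole zebrafish larvae of the AB wild-type strain at 120 hours post fertilization (hpf). The larvae had been exposed to methylparaben (MtP), ethylparaben (EtP) or propylparaben (PrP), preservatives that are esters of p-hydroxybenzoic acid and differ in the length of the alkyl chain, or were untreated controls. Each compound was given at 3 dose labels, BMD5, BMD5/10 and BMD5/50. With 3 libraries in each of the 9 treated groups and 3 control libraries, the series held 30 libraries in 10 groups. The concentrations behind the labels are not given in the sources used here, so compounds were compared at matched labels and not at matched concentrations. The total read count per library ran from 9711814 (EtP BMD5 replicate 1) to 24468093 (EtP BMD5/50 replicate 3), and 18543 genes had enough reads to be tested. The title of the series poses the question whether the compounds differ in how they affect the developing nervous system. Genes of neurons, glia and myelin were therefore looked at in every comparison, beside markers of the other tissues of a whole larva.

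The first principal component set the libraries numbered 1 apart from the others. Liver, digestive and epidermal genes were lower in the libraries numbered 1, in a fit that averages over the 10 groups. All 47 tested genes of the liver and plasma protein list fell in replicate 1 against the mean of replicates 2 and 3, with a median log2 difference of -2.30. Of the exocrine pancreas list, which holds digestive enzymes, 25 of 26 genes fell (median -2.87), and of the intestine list 28 of 31 fell (median -1.58). The epidermis list fell in 49 of 50 genes (median -1.26) and the skeletal muscle list in 56 of 58 (median -1.0). Neuronal and photoreceptor genes went the other way, with 29 of 39 genes of the neuronal list and 37 of 53 phototransduction genes higher in replicate 1 (medians 0.30 and 0.34). By group, the liver score of replicate 1 minus the mean of replicates 2 and 3 was -0.18 in Control and between -3.54 and -0.97 in the treated groups. For the intestine score it was -0.69 in Control and -2.69 to -0.59 in the treated groups, and for the exocrine pancreas score -1.75 and -5.05 to -0.60. In all, 10461 of the 18543 genes differed between replicate 1 and the other replicates at an adjusted p under 0.05 (edgeR), 5076 higher and 5385 lower, against 16 genes between replicates 2 and 3. With an estimated correlation between genes, the smallest adjusted p of a list in this contrast was 0.139. Transcripts annotated as retained introns took 1.05 to 1.3% of the reads in replicate 1 and 0.713 to 1.11% in replicates 2 and 3. The first principal component of log2 CPM held 40.8% of the variance and placed the replicate 1 libraries between -76.1 and -23.8, below all others (-4.14 to 54.8). Among libraries numbered 2 and 3 EtP lay above Control and MtP on it, with the 6 EtP libraries at 41.5 to 54.8, PrP at 4.4 to 43.4, MtP at -4.14 to 16.2 and Control at 4.31 and 14.6. The second held 9.17%.

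**Figure D1:**
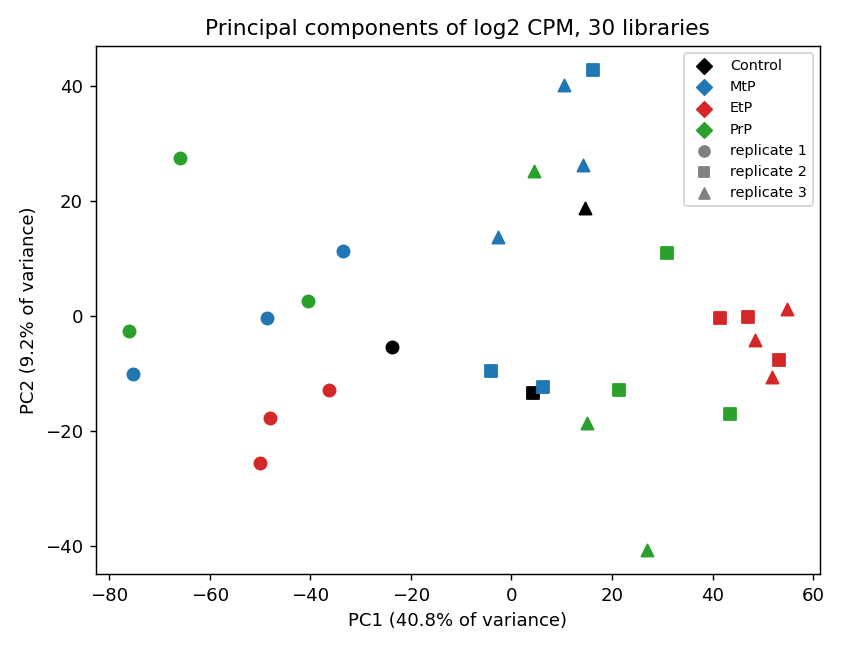
Principal components of log2 CPM of the 30 libraries, with the first component (40.8% of the variance) on the horizontal axis and the second (9.17%) on the vertical axis; colours mark the compound and symbols the replicate number. The libraries numbered 1 lie at the left, between -76.1 and -23.8, and the others between -4.14 and 54.8.

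In larvae exposed to MtP at BMD5, photoreceptor genes lay above the controls. Of 53 tested phototransduction genes, 51 had a positive log2 fold change, with a median of 0.33 (adjusted p = 9.39e-19, adjusted p = 0.524 with an estimated correlation). Examples were sagb, which encodes an arrestin (0.70 ± 0.24 SE), rlbp1b, a retinaldehyde-binding protein (0.62 ± 0.22), and the green opsin opn1mw3 (1.63 ± 0.67). Keratinocyte genes leaned lower, with 48 of 50 genes of the epidermis list below Control (median -0.43, adjusted p = 1.29e-09, adjusted p = 0.919 with an estimated correlation). One of them was the tight junction gene cldnb (-1.07 ± 0.47). Genes of inflammation were also lower in 29 of 34 members (median -0.21, adjusted p = 7.64e-05, 0.524 as adjusted p with an estimated correlation). Those with the smallest p were the prostaglandin synthases ptgs2b (-1.47 ± 0.47) and ptgs2a (-1.34 ± 0.53) and the cytokine signalling inhibitor socs3a (-1.38 ± 0.56). The cell cycle list leaned higher in 49 of 59 members (median 0.12, adjusted p = 3.44e-06, adjusted p = 0.919 with an estimated correlation). The replication licensing genes cdc6 (0.44 ± 0.17) and mcm5 (0.27 ± 0.12) were among them. Without MtP BMD5 replicate 1 the epidermis and cell cycle calls ended (highest adjusted p 0.882 and 0.260), and without Control replicate 1 that of inflammation (0.173), while that of phototransduction stood without each library in turn. Replicate by replicate the phototransduction score, the mean log2 CPM of the list, differed from Control by 0.83, 0.19 and -0.05, and the epidermis score by -1.31, -0.37 and -0.06.

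Nervous system genes differed little between MtP BMD5 and Control. The neuronal list had 29 of 39 members above Control with a median of 0.08 (adjusted p = 0.0168, adjusted p = 0.919 with an estimated correlation). This call ended without MtP BMD5 replicate 1, Control replicate 2 or Control replicate 3 (highest adjusted p 0.556). The score of that list differed by 0.07 with a 95% interval from -0.23 to 0.37, which includes the spread between replicate numbers. In replicates 1, 2 and 3 the score was 6.22, 6.11 and 5.88 with MtP and 6.20, 5.97 and 5.83 in Control. The neurotransmitter score differed by 0.05 (-0.20 to 0.29; adjusted p = 0.118, 0.0229 with the replicate block), that of axon guidance by -0.01 (-0.25 to 0.22) and that of glia and myelin by 0.05 (-0.07 to 0.18). Of single genes, the neuronal RNA-binding protein elavl3 had a log2 fold change of -0.14 (95% interval -0.58 to 0.30), from 93.1 ± 19.4 CPM (SD, n = 3) in Control to 84.6 ± 12.7 CPM. The myelin gene mbpa had 0.03 ± 0.31 (SE), the astroglial gene gfap 0.01 ± 0.31, and acetylcholinesterase, ache, -0.05 ± 0.13. The other sentinel genes were within their errors of Control too. The values were 0.30 ± 0.61 for cyp1a, a target of the aryl hydrocarbon receptor, -0.32 ± 0.40 for the fast muscle light chain mylpfa, -0.15 ± 1.05 for the liver fatty acid binding protein fabp10a and 0.37 ± 1.35 for trypsin, prss1. They were -0.33 ± 0.49 for the clock gene per1b, -0.27 ± 0.68 for the chaperone hsp70.3 and -0.32 ± 0.52 for the cytokine il1b. In edgeR's test 0 of 18543 genes had an adjusted p under 0.05, 233 had an unadjusted p under 0.05 where 927 would be expected by chance, and DESeq2 also called 0 genes. Adjusted over the list alone, 1 gene passed, hsd17b7 of sterol biosynthesis (0.62 ± 0.16), and it no longer passed without Control replicate 2, MtP BMD5 replicate 1 or MtP BMD5 replicate 3. The 95% interval of a gene's log2 fold change reached a median of 0.52 to either side of it, and 66.8% of the genes had intervals within 1 log2 unit of 0.

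At EtP BMD5 genes made in the liver, intestine and heart lay above Control on average over the libraries. Of the 47 liver and plasma protein genes, 46 had a positive log2 fold change, with a median of 1.78 (adjusted p = 1.51e-18, adjusted p = 0.862 with an estimated correlation). Among them were complement component c3a.3 (2.44 ± 1.07 SE), the fetuin gene ahsg1 (1.58 ± 0.72), heparin cofactor serpind1 (2.07 ± 0.98) and the vitamin D binding protein gc (2.69 ± 1.24). Intestinal genes were higher in 29 of 31 members (median 1.12, adjusted p = 4.33e-09, adjusted p = 0.862 with an estimated correlation). Among them were the peptide transporter slc15a1b (1.89 ± 0.81) and the chitinase chia.1 (2.37 ± 1.04). Heart genes were higher in 16 of 18 members (median 0.82, adjusted p = 1.24e-04, adjusted p = 0.862 with an estimated correlation). The natriuretic peptide nppa stood at 3.90 ± 1.73 and the myosin light chain myl7 at 2.77 ± 1.4. Of the genes of xenobiotic metabolism 32 of 39 were higher (median 0.62, adjusted p = 8.18e-05, 0.862 as adjusted p with an estimated correlation), for example the sulfotransferase sult1st3 (2.12 ± 1.03). Ribosomal protein genes lay below Control in 82 of 83 members (median -0.19, adjusted p = 3.62e-14, adjusted p = 0.862 with an estimated correlation).

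These tissue groups moved apart by replicate number. The liver score of EtP BMD5 differed from the control library of the same number by -0.52 in replicate 1, 2.31 in replicate 2 and 1.68 in replicate 3. The mean difference of 1.16 had a 95% interval from -1.16 to 3.47. The heart score differed by 0.16, 1.02 and 0.94 and the ribosomal protein score by 0.05, -0.25 and -0.31. When the libraries numbered 1 were left out, a choice made after the data were seen, 68 genes had an adjusted p under 0.05, 66 of them higher with EtP and 25 of them in the liver list. Vitamin D binding protein gc rose by 3.29 ± 0.43 (SE; adjusted p = 0.00878), c3a.3 by 2.89 ± 0.39 (adjusted p = 0.00878) and apolipoprotein apoa2 by 3.0 ± 0.46 (adjusted p = 0.0145), each with 2 libraries per group. The liver list had an adjusted p of 0.0499 with an estimated correlation in those libraries. Liver, intestine and ribosomal protein calls on all libraries stood without each library in turn. That of the heart list ended without Control replicate 1 (adjusted p = 0.0531) and that of xenobiotic metabolism without EtP BMD5 replicate 2 or 3 (highest adjusted p 0.145).

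Neuronal, neurotransmitter and axon guidance scores of the EtP BMD5 larvae lay near Control, while glia and myelin genes leaned higher. The neuronal score differed by 0.03 (95% interval -0.27 to 0.33), the neurotransmitter score by 0.01 (-0.23 to 0.26) and the axon guidance score by -0.01 (-0.24 to 0.22). Glia and myelin genes were higher in 19 of 26 members (median 0.11, adjusted p = 0.00348, adjusted p = 0.0822 with an estimated correlation), with a score difference of 0.16 (0.04 to 0.28). The call ended without EtP BMD5 replicate 1 (adjusted p = 0.221). Among the members were the myelin protein genes mpz (0.71 ± 0.24) and plp1b (0.36 ± 0.12). Of the sentinel genes, mbpa, at 48.2 ± 8.33 CPM (SD, n = 3) in Control, had a log2 fold change of 0.54 with a 95% interval from -0.11 to 1.19. The log2 fold change was 0.43 ± 0.31 for gfap, 0.15 ± 0.13 for ache and -0.08 ± 0.21 for elavl3. For cyp1a the values were 3.42 ± 1.08 CPM in Control and 6.63 ± 3.47 CPM with EtP (0.97, 95% interval -0.29 to 2.22), and for fabp10a 78.6 ± 10.8 and 241 ± 170 CPM (1.61 ± 1.07). The remaining log2 fold changes were 1.49 ± 1.37 for prss1, 0.99 ± 0.68 for hsp70.3, -0.15 ± 0.40 for mylpfa, 0.19 ± 0.49 for per1b and 0.10 ± 0.51 for il1b. Over all libraries edgeR called 0 genes, with 380 at an unadjusted p under 0.05, DESeq2 called 0, and 0 passed when adjusted over the list alone. Intervals lay within 1 log2 unit of 0 for 66.2% of the genes.

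**Figure D2:**
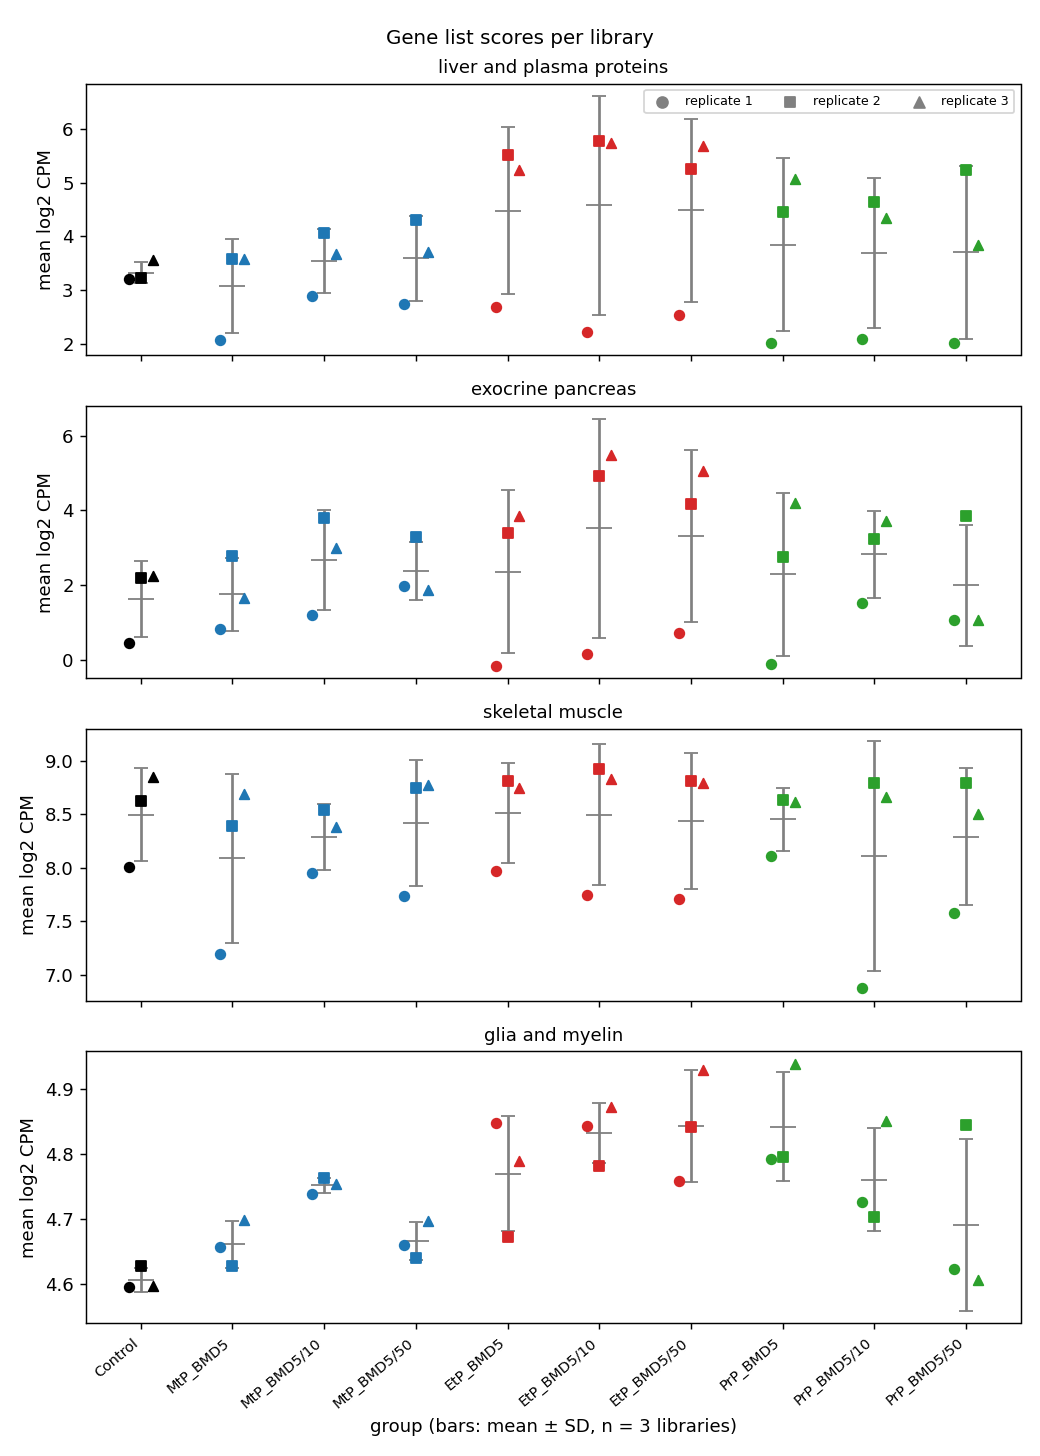
Score of 4 gene lists (mean log2 CPM of the members, vertical axes) in each of the 30 libraries by group (horizontal axis), with symbols for the replicate number and grey bars for the mean ± SD of 3 libraries. In the liver panel the EtP libraries numbered 2 and 3 lie between 5.24 and 5.77 and those numbered 1 between 2.22 and 2.68.

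PrP at BMD5 went with higher glial and photoreceptor genes and lower ribosomal protein genes. The glia and myelin list was above Control in 18 of 26 members with a median of 0.14 (adjusted p = 1.71e-04, adjusted p = 0.0104 with an estimated correlation). Its score rose by 0.24 (95% interval 0.11 to 0.36), by 0.20, 0.17 and 0.34 in the replicates taken by number. Members with the smallest p were the myelin proteolipid gene plp1b (0.37 ± 0.12 SE), the oligodendrocyte transcription factor olig1 (0.57 ± 0.24), the myelin regulatory factor myrf (1.79 ± 0.78) and her4.1, a Notch target of radial glia (0.47 ± 0.20). Phototransduction genes were higher in 47 of 53 members (median 0.29, adjusted p = 1.87e-10, adjusted p = 0.95 with an estimated correlation). Recoverin, rcvrna (0.55 ± 0.21), and the guanylate cyclase gucy2d (0.60 ± 0.28) were among them. Of 83 ribosomal protein genes 81 were lower (median -0.20, adjusted p = 1.09e-16, adjusted p = 0.95 with an estimated correlation), rplp2 by -0.33 ± 0.15. Their score differed by -0.01, -0.09 and -0.46 by replicate, so the gap lay mostly in replicate 3, a library that stood apart in its composition. Intestine and liver lists leaned higher in 28 of 31 and 45 of 47 members (adjusted p = 2.10e-06 and 4.04e-06, both 0.95 as adjusted p with an estimated correlation). Both calls ended without PrP BMD5 replicate 3 (adjusted p = 0.538 and 0.836). The estimated-correlation call of the glia list held in the fits that left out Control replicate 3 or PrP BMD5 replicate 2 and not in the other 4 (adjusted p 0.0161 to 0.201).

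Other neural scores of the PrP BMD5 larvae differed from Control by 0.09 for neuronal genes (95% interval -0.21 to 0.39), 0.05 for neurotransmitter systems (-0.19 to 0.30) and 0.15 for axon guidance (-0.08 to 0.39). Among the sentinels elavl3 had 0.07 (95% interval -0.37 to 0.51), mbpa 0.32 ± 0.31, gfap 0.53 ± 0.31 and ache 0.14 ± 0.13. The level of ache was 168 ± 15.1 CPM (SD, n = 3) in Control and 186 ± 10 CPM with PrP. The others were cyp1a at 0.73 ± 0.62, fabp10a at 0.94 ± 1.05, prss1 at 1.43 ± 1.37, mylpfa at -0.15 ± 0.40, per1b at 0.15 ± 0.49, hsp70.3 at -0.29 ± 0.69 and il1b at -0.08 ± 0.53. No adjusted p was under 0.05 (edgeR 0 genes, 344 at an unadjusted p under 0.05, DESeq2 0 genes), and 0 genes passed when adjusted over the list alone. In this comparison 66.0% of the intervals lay within 1 log2 unit of 0. One library of this group stood apart: in PrP BMD5 replicate 3 the unnamed gene zgc:158463 held 79314 CPM and CT027638.1 held 76734 CPM, against at most 15750 and 14851 CPM elsewhere. The deposited table places cyp1a at 5588068 to 5598958 of chromosome 18, elavl3 at 46800190 to 46818001 of chromosome 3, and mbpa at 21814047 to 21832630 of chromosome 19, in a genome build not given in the sources used here. It places gfap at 31792441 to 31804481 of chromosome 3, ache at 26077153 to 26087807 of chromosome 7, fabp10a at 52512025 to 52516915 of chromosome 16 and plp1b at 23268121 to 23280098 of chromosome 5.

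At the lower labels of MtP, replication and photoreceptor genes again lay above Control. At BMD5/10 the cell cycle list was higher in 52 of 59 members (median 0.14, adjusted p = 1.71e-09, adjusted p = 0.708 with an estimated correlation). Phototransduction genes were higher in 47 of 53 (median 0.26, adjusted p = 1.71e-09, 0.708 as adjusted p with an estimated correlation). Glia and myelin genes were higher in 21 of 26 members (median 0.12, adjusted p = 0.00276, adjusted p = 0.0635 with an estimated correlation). Epidermis genes were lower in 45 of 50 (median -0.44, adjusted p = 2.77e-06, adjusted p = 0.924 with an estimated correlation). These 4 calls stood without each library in turn. Neuronal genes were higher in 31 of 39 members at BMD5/10 (median 0.14, adjusted p = 0.00276, adjusted p = 0.924 with an estimated correlation), a call that ended without Control replicate 3 (0.210). The cell cycle list was higher in 45 of 59 members at BMD5/50 (median 0.13, adjusted p = 6.12e-04, adjusted p = 0.976 with an estimated correlation), and not without MtP BMD5/50 replicate 1 (0.0548). At BMD5/50 the phototransduction list was higher in 47 of 53 members (median 0.31, adjusted p = 2.52e-08, adjusted p = 0.976 with an estimated correlation), by 0.62, 0.07 and 0.01 in the replicates. The call ended without MtP BMD5/50 replicate 1 (adjusted p = 0.0563). Axon guidance genes leaned lower there, with 9 of 31 members above Control (median -0.08, adjusted p = 0.0165, adjusted p = 0.976 with an estimated correlation), by -0.01, -0.43 and -0.20 in the replicates. Glia and myelin genes leaned higher in 19 of 26 (median 0.17, adjusted p = 0.0436, 0.591 as adjusted p with an estimated correlation). These neural calls stood in 2 and 1 of the 6 fits without 1 library (highest adjusted p 0.192 and 0.122). Genes with an adjusted p under 0.05 numbered 0 at both labels in edgeR and in DESeq2, with 336 and 877 at an unadjusted p under 0.05. The smallest adjusted p at BMD5/50 was 0.213. Adjusted over the list alone, none passed at BMD5/10 and 1 at BMD5/50, the sterol synthesis gene fdps (0.36 ± 0.09), whose call ended without Control replicate 1 or 2.

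At EtP BMD5/10 pancreatic, hepatic and intestinal genes lay above Control in the libraries numbered 2 and 3, and myelin genes leaned higher. All 26 exocrine pancreas genes had positive log2 fold changes with a median of 3.17 (adjusted p = 8.36e-16, adjusted p = 0.815 with an estimated correlation). Of these, 22 passed when adjusted over the list alone, among them carboxypeptidase cpa4 (3.08 ± 1.1 SE), trypsin-like prss59.1 (4.11 ± 1.55), the disulfide isomerase pdia2 (3.1 ± 1.19) and amylase amy2a (3.48 ± 1.38). The liver list was higher in 46 of 47 members (median 2.11, adjusted p = 6.66e-20, adjusted p = 0.815 with an estimated correlation). The intestine list was higher in 28 of 31 (median 1.66, adjusted p = 7.72e-14, 0.815 as adjusted p with an estimated correlation). Glia and myelin genes rose as a list (18 of 26 higher, median 0.09, adjusted p = 7.76e-05, adjusted p = 0.0074 with an estimated correlation). The score difference was 0.23 (95% interval 0.10 to 0.35), with replicate values of 0.25, 0.15 and 0.28. The estimated-correlation call ended without Control replicate 2 or EtP BMD5/10 replicate 1 (highest adjusted p 0.309). The myelin gene plp1b passed when adjusted over the list alone and rose by 0.55 ± 0.12, as did the myelin gene mpz by 0.93 ± 0.24 and olig1 by 0.85 ± 0.23. The same adjustment passed insulin, ins (3.02 ± 0.85), the neurofilament genes nefla (0.64 ± 0.19), neflb (0.65 ± 0.21) and nefma (0.89 ± 0.25), and the tubulin gene tubb2 (0.40 ± 0.12). Of these 30 genes only plp1b passed in each fit that left out 1 library, and the exocrine genes passed in only 1 of 6 such fits, that without EtP BMD5/10 replicate 1. The liver score differed from Control by -0.98 in replicate 1, 2.56 in replicate 2 and 2.18 in replicate 3, and the exocrine pancreas score by -0.31, 2.74 and 3.24 in the same order.

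Glial genes rose as a list at EtP BMD5/50 too, with 20 of 26 members higher (median 0.11, adjusted p = 2.22e-05, adjusted p = 0.0038 with an estimated correlation). The score difference was 0.24 (95% interval 0.12 to 0.36), with replicate values of 0.16, 0.21 and 0.33. This call held without each library in turn (adjusted p 0.00925 to 0.0445 with an estimated correlation). Adjusted over the list alone, plp1b rose by 0.56 ± 0.12 SE, mpz by 0.82 ± 0.24 and olig1 by 0.81 ± 0.23. Of these, plp1b missed the threshold only without EtP BMD5/50 replicate 3 (adjusted p = 0.121). Liver genes were higher in 45 of 47 members (median 1.90, adjusted p = 1.61e-17, adjusted p = 0.796 with an estimated correlation). Exocrine pancreas genes were higher in 26 of 26 (median 2.65, adjusted p = 2.53e-13, 0.796 as adjusted p with an estimated correlation). Liver score differences were -0.68, 2.04 and 2.13 by replicate. Neuronal genes leaned higher in 22 of 39 members (median 0.04, adjusted p = 0.00371, adjusted p = 0.899 with an estimated correlation). That call ended without Control replicate 2, Control replicate 3 or EtP BMD5/50 replicate 1 (highest adjusted p 0.884). Over all genes and all libraries edgeR and DESeq2 called 0 genes at either lower EtP label, with 679 at BMD5/10 and 527 at BMD5/50 at an unadjusted p under 0.05. In replicates 2 and 3 alone, a choice made after the data were seen, 393 genes passed at BMD5/10 (341 higher) and 120 at BMD5/50 (114 higher). At BMD5/10 fabp10a rose by 2.32 ± 0.31 (adjusted p = 0.00244), ins by 3.11 ± 0.48 (adjusted p = 0.00423) and plp1b by 0.64 ± 0.15 (adjusted p = 0.0341).

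PrP at BMD5/10 went with lower ribosomal protein genes and higher photoreceptor genes. There 81 of 83 ribosomal protein genes were lower (median -0.32, adjusted p = 4.93e-32, adjusted p = 0.783 with an estimated correlation). Examples were rpl29 (-0.46 ± 0.16 SE) and rps28 (-0.44 ± 0.17), and the list had score differences of -0.19, -0.29 and -0.43 by replicate. Phototransduction genes were higher in 51 of 53 members (median 0.45, adjusted p = 3.38e-21, adjusted p = 0.531 with an estimated correlation), by 0.88, -0.01 and 0.28 in the replicates. Among them were the rhodopsin kinase grk1b (0.69 ± 0.20) and the blue opsin opn1sw2 (0.57 ± 0.19). Replicate 1 of this group held 7.87% mitochondrial reads and lay lowest of all libraries on the first principal component (-76.1). Glia and myelin genes rose as a list (20 of 26 higher, median 0.14, adjusted p = 8.40e-04, adjusted p = 0.0299 with an estimated correlation). With the replicate number as a block the latter was 0.0585, and in the fits without 1 library it held only without Control replicate 3 (0.0481 to 0.293). Neuronal genes were higher in 28 of 39 members (median 0.11, adjusted p = 0.0072, adjusted p = 0.842 with an estimated correlation), a call kept in 3 of 6 fits without 1 library (highest adjusted p 0.889). Adjusted over the list alone, 4 inflammation genes fell: socs3a by 1.96, ptgs2b by 1.59, ptgs2a by 1.63 and the NF-kappaB inhibitor nfkbiaa by 0.85 on the log2 scale. None of the 4 passed without Control replicate 1, PrP BMD5/10 replicate 1 or PrP BMD5/10 replicate 3. With the replicate number as a block, more genes passed by this adjustment. At BMD5/50 only 5 of 83 ribosomal protein genes lay above Control, and the median was -0.09 (adjusted p = 0.00391, adjusted p = 0.988 with an estimated correlation). Their score differed by 0.04, -0.23 and -0.06 by replicate, and the call stood in 2 of 6 fits without 1 library (highest adjusted p 0.866), with the direction turned in 2 of them. Phototransduction genes were higher in 49 of 53 members (median 0.35, adjusted p = 1.55e-12, 0.988 as adjusted p with an estimated correlation), by 0.73, -0.10 and 0.16. This ended without PrP BMD5/50 replicate 1 (0.367). Glia and myelin genes were higher in 19 of 26 (median 0.13, adjusted p = 0.0178, adjusted p = 0.212 with an estimated correlation), and not without Control replicate 2 or PrP BMD5/50 replicate 2 (highest adjusted p 0.205). At BMD5/50 lens genes were lower in 31 of 41 members (median -0.36, adjusted p = 1.40e-10, adjusted p = 0.988 with an estimated correlation), by -0.77, 0.26 and -0.41 by replicate. This call ended without Control replicate 3 or PrP BMD5/50 replicate 1 (highest adjusted p 0.554). All 13 genes of the mitochondrial genome were higher there (median 0.19, adjusted p = 3.13e-04, 0.988 as adjusted p with an estimated correlation). Mitochondrial reads made up 9.39% of PrP BMD5/50 replicate 1, more than in any other library. That call ended without Control replicate 1 or PrP BMD5/50 replicate 1 (highest adjusted p 0.340). In edgeR 0 genes passed at both labels, as in DESeq2, with 464 and 291 at an unadjusted p under 0.05.

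Between compounds at BMD5, EtP larvae had higher liver and lower cell cycle genes than MtP larvae. All 47 liver genes were higher (median 1.81, adjusted p = 1.17e-16, adjusted p = 0.622 with an estimated correlation), gc by 2.85 ± 1.25 SE, and the score differed by 0.62, 1.94 and 1.67 in the replicates. Of the cell cycle genes 57 of 59 were lower (median -0.22, adjusted p = 7.97e-13, 0.622 as adjusted p with an estimated correlation), such as the mitotic activator cdc20 (-0.42 ± 0.15) and the microtubule regulator stmn1a (-0.34 ± 0.13). Both calls stood without each library in turn. PrP larvae differed from MtP larvae in the same list of cell cycle genes (53 of 59 lower, median -0.17, adjusted p = 2.64e-11, adjusted p = 0.799 with an estimated correlation). The cell cycle scores of replicates 1, 2 and 3 were 4.84, 4.51 and 4.77 with MtP and 4.60, 4.55 and 4.37 with EtP. With PrP they were 4.58, 4.60 and 4.44, so in replicate 2 MtP lay below both other compounds. Compared with EtP larvae, PrP larvae had lower epidermis genes (49 of 50, median -0.46, adjusted p = 1.33e-09, adjusted p = 0.833 with an estimated correlation). Phototransduction genes were higher in the same pair (52 of 53, median 0.23, adjusted p = 6.23e-09, 0.833 as adjusted p with an estimated correlation). For the ethyl against the methyl ester, the neuronal score differed by -0.04 (95% interval -0.34 to 0.26), and that of neurotransmitter systems by -0.03 (-0.28 to 0.22). The axon guidance score differed by 0.01 (-0.23 to 0.24) and that of glia and myelin by 0.11 (-0.01 to 0.23). For the propyl against the methyl ester these were 0.02 (-0.28 to 0.32), 0.01 (-0.24 to 0.26), 0.17 (-0.06 to 0.40) and 0.18 (0.06 to 0.30) in the same order. The last had an adjusted p of 0.0299, 0.0587 with the replicate block and 0.421 as adjusted p with an estimated correlation, and stood in 2 of 6 fits without 1 library (highest adjusted p 0.178). For the propyl against the ethyl ester they were 0.06 (-0.25 to 0.36), 0.04 (-0.21 to 0.29), 0.16 (-0.07 to 0.39) and 0.07 (-0.05 to 0.19). Axon guidance genes were higher in 23 of 31 members in that pair (median 0.05, adjusted p = 0.0193, adjusted p = 0.833 with an estimated correlation), a call kept in 2 of 6 fits without 1 library (highest adjusted p 0.65). In edgeR and DESeq2 0 genes differed between any pair, with 709, 446 and 327 genes at an unadjusted p under 0.05. When adjusted over the list alone 1 gene passed, the AP-1 gene fosl1a, lower with PrP than with EtP (-2.26 ± 0.62). It did not pass without EtP BMD5 replicate 1 or any 1 of the PrP BMD5 libraries. In replicates 2 and 3 alone 63 genes differed between EtP and MtP (61 higher with EtP) and 0 in the other pairs.

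At BMD5/10 and BMD5/50 the compounds again parted in liver, cell cycle and eye genes. At BMD5/10 all 47 liver genes were higher with EtP than with MtP (median 1.71, adjusted p = 1.89e-14, adjusted p = 0.838 with an estimated correlation), with score differences of -0.68, 1.72 and 2.06 by replicate. There 53 of 59 cell cycle genes were lower (median -0.17, adjusted p = 8.20e-11, 0.838 as adjusted p with an estimated correlation). In the fit with the replicate block, 1 gene passed over all genes in that pair, the mitochondrial carrier slc25a48 (1.05 ± 0.15 SE, adjusted p = 0.00407), which the unblocked fit put at 1.06 ± 0.33. It lies at 25590603 to 25599002 of chromosome 14 in the deposited table. In replicates 2 and 3 alone 482 genes differed between EtP and MtP at this label, 422 of them higher with EtP. PrP larvae had higher mitochondrial genome genes than MtP larvae (13 of 13, median 0.17, adjusted p = 2.42e-07, adjusted p = 0.985 with an estimated correlation). At BMD5/50 lens genes were lower with PrP than with MtP in 39 of 41 members (median -0.46, adjusted p = 1.18e-25, adjusted p = 0.391 with an estimated correlation), by -1.24, -0.20 and -0.21 in the replicates. Among them were the crystallins cryba2a (-0.56 ± 0.23) and crygm2b (-0.75 ± 0.32). Axon guidance genes were higher with EtP than with MtP at BMD5/50 in 23 of 31 members (median 0.15, adjusted p = 0.00389, adjusted p = 0.943 with an estimated correlation), by 0.15, 0.30 and 0.33 in the replicates. With PrP against EtP they leaned lower (12 of 31 higher, median -0.14), as did neuronal genes (16 of 39 higher, median -0.04), both at an adjusted p of 0.0374 and 0.802 as adjusted p with an estimated correlation. Each of these 3 calls stood in 3 of 6 fits without 1 library (highest adjusted p 0.274, 0.857 and 0.857). The number of lists called between PrP and MtP at BMD5/50 was 3, and 7 with the replicate block. Adjusted over the list alone, klf9, a target of thyroid and glucocorticoid hormones, was higher with EtP than with MtP (2.26 ± 0.68). By the same adjustment the neurofilament genes nefla (-0.75 ± 0.19) and nefma (-0.89 ± 0.26) were lower with PrP than with EtP. Each of the 3 passed in only 2 of the 6 fits without 1 library. Over all genes 0 passed in edgeR and in DESeq2 in these 6 pairs, with 225 to 1296 at an unadjusted p under 0.05.

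Between the highest and lowest labels of each compound, lens genes differed as a list, lower at BMD5 with MtP and EtP and higher with PrP. With MtP the list lay lower than at BMD5/50 (40 of 41 members, median -0.34, adjusted p = 5.13e-12, adjusted p = 0.944 with an estimated correlation). With EtP it was lower too (40 of 41, median -0.26, adjusted p = 3.18e-09, adjusted p = 0.985 with an estimated correlation), and with PrP higher (40 of 41, median 0.46, adjusted p = 2.79e-17, adjusted p = 0.967 with an estimated correlation). The 3 calls stood without each library in turn. By replicate number the score differed by -0.32, -0.53 and -0.26 with MtP, -0.48, -0.03 and -0.29 with EtP, and 1.28, -0.23 and 0.58 with PrP, so replicate 2 of PrP went the other way. Axon guidance genes were higher at MtP BMD5 than at MtP BMD5/50 in 25 of 31 members (median 0.11, adjusted p = 8.14e-04, adjusted p = 0.944 with an estimated correlation), a call that ended without MtP BMD5 replicate 1 or MtP BMD5/50 replicate 2 (highest adjusted p 0.143). For EtP 11 of 39 neuronal genes were higher (median -0.07, adjusted p = 0.00859, 0.985 as adjusted p with an estimated correlation), and that call stood in 3 of 6 fits without 1 library (highest adjusted p 0.811). Axon guidance genes were higher at PrP BMD5 than at PrP BMD5/50 in 22 of 31 members (median 0.07, adjusted p = 0.00153, 0.967 as adjusted p with an estimated correlation). When adjusted over the list alone the adhesion genes cntn2 (1.67 ± 0.44 SE) and l1camb (2.3 ± 0.65) passed, while the oxidase subunit noxo1a was lower (-1.18 ± 0.30). The list call ended without PrP BMD5/50 replicate 2 or 3 (highest adjusted p 0.0564), and neither adhesion gene passed without PrP BMD5 replicate 3, PrP BMD5/50 replicate 1 or PrP BMD5/50 replicate 3. With edgeR 0 genes passed in the 3 comparisons, as with DESeq2, and 365, 153 and 645 had an unadjusted p under 0.05 for MtP, EtP and PrP.

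Over the 735 pairs of a list and a comparison, 247 list tests passed with the preset correlation, 146 of them upward, and 4 with an estimated one, all of glia and myelin genes. Of the 247 calls, 55 stood without each library in turn. Lists of endocrine pancreas, fatty acid synthesis, neurotransmitter, interferon, sterol synthesis, thyroid axis and unfolded protein response genes passed in none of the 21 comparisons.

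Fold changes of the compounds against the shared controls were correlated across genes, as unchanged groups set against the same 3 control libraries would also be. At BMD5 Pearson's r was 0.23 between MtP and EtP, 0.35 between MtP and PrP and 0.54 between EtP and PrP, over 18543 genes that are not independent replicates. In 20 simulations without any treatment or replicate effect the mean r was 0.51, 0.50 and 0.49. The covariance was 0.03, 0.04 and 0.08, against 0.09 in each of the simulated pairs. The spread between replicate numbers entered these simulations as independent noise, so their covariance may lie too high as a reference. At BMD5/10 r was 0.44, 0.61 and 0.60 in the same order of pairs and 0.51, 0.50 and 0.50 in the simulations, and at BMD5/50 it was 0.40, 0.56 and 0.56 against 0.52, 0.51 and 0.51. The observed covariance minus the simulated one lay between -0.064 and 0.009 over the 9 pairs and above 0 in 1 of them. For the fit with the replicate block, a replicate effect alike in all groups was simulated. The mean simulated covariance was then 0.060 against 0.094 without it. There the difference lay between -0.031 and 0.033, above 0 in 7 of 9 pairs. In replicates 2 and 3 it lay between -0.029 and 0.075, above 0 in 7 of 9. With 3 control libraries the controls could not be split, so part of any excess may come from the shared controls, and overlaps of called genes could not be formed because 0 genes were called.

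The authors' deposited table also holds fold changes and calls per transcript for each treated group. Transcripts called in the authors' deposited table number 349, 469 and 580 for MtP at BMD5, BMD5/10 and BMD5/50, 574, 780 and 801 for EtP, and 451, 415 and 361 for PrP. Those with a q under 0.05 in the authors' deposited table number 24, 57 and 43 for MtP, 32, 51 and 59 for EtP, and 27, 24 and 22 for PrP. Of the 47 liver list symbols, the authors' deposited table calls 33, 36 and 36 higher with EtP, 0 at each label with MtP and 7, 2 and 5 with PrP. Exocrine pancreas symbols called higher in the authors' deposited table number 0, 21 and 20 of 30 with EtP. For the myelin gene plp1b at EtP BMD5/10 the authors' deposited table gives a log2 fold change of 2.69 (q = 9.25e-04) for 1 transcript. For the brain creatine kinase ckbb the authors' deposited table gives 1.22 at MtP BMD5/50 (q = 1.71e-06) and 1.12 at EtP BMD5/50 (q = 3.27e-05). For sdha, a subunit of succinate dehydrogenase, a transcript has -9.09, -9.33 and -9.69 in the EtP groups of the authors' deposited table. These are values of 1 transcript and not of the whole gene. Changes of such size were common there. Of the EtP transcripts with a q under 0.05, 24 of 32, 33 of 51 and 33 of 59 had a log2 fold change of 5 or more in size.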

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

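All tests of explanations below were chosen after the result was seen, except that of a few genes taking most of the counts and the regroupings of the libraries.

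The score of the glucocorticoid and stress axis list lay below the control mean in every MtP library at BMD5 and above it in every EtP library, with a mean difference of -0.30 for MtP (-0.53 to -0.16 in the 3 libraries) and 0.23 for EtP (0.08 to 0.46), a gap of -0.54. The list, which holds targets of the cortisol receptor and genes of cortisol synthesis, was picked out for that, among 46 values for each of 3 pairs of compounds, and the difference was not tested by that rule. Against Control the list test gave an adjusted p of 0.0416 with MtP (0.524 as adjusted p with an estimated correlation), which ended without Control replicate 1 or MtP BMD5 replicate 3, and of 0.0648 with EtP (0.862), which did not pass. In the direct comparison of EtP with MtP the list had 12 of 17 members higher (median 0.57, adjusted p = 8.55e-04, adjusted p = 0.294 with an estimated correlation). With the preset correlation that call ended without MtP BMD5 replicate 3 (adjusted p = 0.153). With an estimated correlation the list passed only in the fit without MtP BMD5 replicate 1 (adjusted p = 0.00861).

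The libraries numbered 1 differed from those numbered 2 and 3 in 10461 of 18543 genes, with lower liver, gut, skin and muscle genes over the groups together, though the liver score of replicate 1 minus that of replicates 2 and 3 was -0.18 in Control and -3.54 to -0.97 in the treated groups. Depth argues little for this, as the library numbered 1 had the smallest total in 5 of 10 groups and the largest in 1. Leaving out the most abundant genes of each library kept 10458 differing genes of 18536. TMM scaling, used in both fits, already limits the weight of such genes, so this cannot decide on a few genes taking most of the counts. A smaller share of muscle RNA would raise liver genes, and their median difference was -2.30 with quartiles of -2.53 and -1.73. A different day, clutch or RNA preparation may lie behind the number, which the labels do not say, and with 1 control group it stays open and untested whether treatment acts on the liver part.

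Liver scores of replicates 2 and 3 were 5.24 to 5.77 with EtP, 3.84 to 5.24 with PrP, 3.57 to 4.31 with MtP and 3.21 and 3.56 in Control, while in replicate 1 every treated library (2.01 to 2.89) lay below Control (3.2). The score of EtP libraries minus Control, MtP and PrP libraries pooled was 0.043 in replicate 1 (95% interval -0.67 to 0.76). It was 1.44 in replicates 2 and 3 (0.90 to 1.99). These intervals take libraries of different compounds and labels as replicates, and the pattern was picked for its split by number. They therefore cannot decide on an effect alike in every replicate. A response in proportion to the label is argued against, since BMD5 minus BMD5/50 was -0.086 in replicates 2 and 3. EtP libraries of the same number deviated together, with a mean correlation of 0.363 (0.287 to 0.476) against 0.0209 for MtP and 0.0160 for PrP. A batch shared by the EtP libraries of a number and an effect of EtP that differs between batches of larvae cannot be told apart, both may add to the pattern, and the compound is confounded with any such batch.

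The glia and myelin list lay above Control in all 9 treated groups, with 24 of 27 treated libraries above every control library. No 1 control library accounts for it, as the difference of 0.15 (95% interval 0.06 to 0.24) stayed at 0.145 or more without each in turn. A larger share of neural RNA stays open: against the neuronal score the difference was 0.10 (-0.13 to 0.33), with the neuronal score itself at 0.05 (-0.17 to 0.28). Chance values of the 3 shared controls cannot be told apart from an effect either, since the exact permutation p of 0.00616 over 4060 regroupings is for a list picked for its small p. A glial response shared by the compounds is a hypothesis that may fit these values and needs other controls.

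Each comparison allows 10 splits of its 6 libraries, too few for a share under 0.05. The real split called 0 genes in all 21 comparisons, all 10 of 10 splits reached that number, and the highest other split also called 0, except for MtP BMD5 against BMD5/50, where it called 0.674% of the 18543 genes. Of 84 other splits with both libraries numbered 1 on the same side, 74 gave more genes at an unadjusted p under 0.05 than the real split, and 42 did of the 5 in each comparison that set them apart. Examples are 4957 against 644 for PrP against EtP at BMD5/50 and 3497 against 365 for MtP BMD5 against BMD5/50. For EtP BMD5/10 against Control some gave fewer, 344 and 630 against 679.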

How the results depend on the processing

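DESeq2 with the replicate block, replicates 2 and 3 alone, each library left out in turn for the lists, and the list tests that join 2 of these settings were chosen only after the results were seen. With RLE scaling, no filter, DESeq2 and only the 6 libraries compared, each of the 21 comparisons kept a count of 0 genes, and leaving out each library in turn gave 0 in every fit (edgeR). The replicate block called 1 gene in EtP BMD5/10 against MtP BMD5/10 (slc25a48) and changed no other gene count. In the 14 comparisons that met the pairing rule it ended 7 of 154 list calls and added 26, with no direction changed. It also ended 1 call with an estimated correlation there (glia and myelin, PrP BMD5/10). Transcripts tested 1 by 1 gave 1 call each at MtP BMD5/50 and EtP BMD5/50, both of ckbb. DESeq2 with the replicate block called 33 genes for EtP BMD5/10, 100 for PrP BMD5/10, 1 for MtP BMD5/50 and 3 for EtP BMD5/50 against Control. Between compounds it called 93 (EtP and MtP at BMD5), 28 (the same pair at BMD5/10), 16 (at BMD5/50) and 1 (PrP and MtP at BMD5/50). Replicates 2 and 3 alone gave 68, 393 and 120 for EtP at BMD5, BMD5/10 and BMD5/50, and 63 and 482 for EtP against MtP at BMD5 and BMD5/10, and 0 in the other 16 comparisons. These libraries have a smaller spread (dispersion 0.0210 against 0.0675 over all libraries), but the replicate block had 0.0260 and called only 1 gene. The cause of the differences between settings was not tested.

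Of 247 list calls, 4 remained with an estimated correlation, 3 with fry, 3 with the block and an estimated correlation, 3 in replicates 2 and 3 with an estimated correlation and 55 without each library in turn. The block alone gave 278 calls and replicates 2 and 3 gave 324. Genes passing when adjusted over the list alone, counted per list and comparison, numbered 46 in the main fit. No adjustment was made across the 735 pairs of a list and a comparison, so some of these would pass by chance. Such genes numbered 653 with the block and 1578 in replicates 2 and 3. For EtP against MtP at BMD5 these counts were 0, 114 and 134. The cause of the rise was not tested. The liver list of MtP BMD5 turned upward in replicates 2 and 3 (adjusted p = 0.0339).

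Outside the fits of replicates 2 and 3 alone, no sentinel gene of a BMD5 group passed under any setting above. In replicates 2 and 3 fabp10a stood at 368 and 307 CPM with EtP BMD5, against 71.8 and 91.1 CPM in Control. Sentinel genes near 0 changed sign between settings, for causes not tested. With MtP, mbpa had -0.014 with the replicate block and -0.019 in DESeq2 with the block, and in replicates 2 and 3 gfap had -0.051, ache 0.027, fabp10a 0.21 and il1b 0.13. With PrP, fabp10a had -0.014 and -0.090 with the block in edgeR and DESeq2. Without 1 library at a time, the MtP log2 fold changes ranged from -0.12 to 0.59 for cyp1a, -0.18 to 0.23 for mbpa, -0.25 to 0.34 for gfap, and -0.10 to 0.046 for ache. They ranged from -0.62 to 0.039 for mylpfa, -0.57 to 0.26 for fabp10a, -0.55 to 0.77 for prss1 and -1.16 to 0.11 for hsp70.3. With EtP they ranged from -0.24 to 0.049 for elavl3, -0.45 to 0.087 for mylpfa, -0.076 to 0.31 for per1b and -0.060 to 0.28 for il1b. With PrP the ranges were -0.085 to 0.20 for elavl3, -0.46 to 0.082 for mylpfa, -0.085 to 0.49 for per1b and -0.70 to 0.30 for il1b, and for ckbb at EtP BMD5/50 it was -1.08e-04 to 0.15. Some sentinel genes had too few reads: vtg1, with 19 reads in all, could not be tested.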

Other observations

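The fits of DESeq2 with the replicate block were chosen after the data were seen, and the tests of transcripts were planned.

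DESeq2 with the replicate block called 93 genes between EtP and MtP at BMD5. Of the epidermis list 5 of them were higher with EtP, evpla by 1.80 on the log2 scale, pkp3a by 1.31, ppl by 1.07, evplb by 1.03 and krt92 by 0.92. Of the heart list the cardiac myosin light chain cmlc1 was higher by 3.71, and by 3.60 at BMD5/10. Of the neuronal list syn1 (-0.25) and sypb (-0.36) were lower. The desmoglein dsg2.1, in no list and picked after the values were seen, was higher by 2.75. The cryptochrome cry3b, a light-dependent clock gene, was lower with EtP than with MtP at each label, by -0.69, -0.62 and -0.56, and lower than in Control at EtP BMD5/10 (-0.57). The mitochondrial carrier slc25a48 was higher with EtP than with MtP at BMD5 (0.84) and BMD5/10 (1.06). On simulated counts with a replicate effect alike in all groups, 13.4% of this tool's calls were false. The share in these data was not tested. Of the genes named, edgeR with the block called only slc25a48, at BMD5/10.

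With PrP at BMD5/10 the same test called 100 genes, 18 of them higher. Ribosomal protein genes made up 49 of those lower, such as rpl15 (-0.45) and rps16 (-0.36). Lower too were 9 epidermis genes, among them the keratin krt91 (-1.08), and 4 skeletal muscle genes, among them the myosin heavy chain myhz2 (-1.15). By number, the epidermis scores were 3.49, 5.59 and 5.22 with PrP BMD5/10 against 4.97, 5.59 and 5.64 in Control. Skeletal muscle scores were 6.88, 8.80 and 8.66 against 8.01, 8.63 and 8.85, so both gaps were largest in replicate 1. Of the phototransduction list 5 were higher, such as grk1b (0.67). Ribosomal, epidermis and muscle genes were also lower in the libraries numbered 1 in the fit over all groups (medians -0.33, -1.26 and -1.0).

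A pair of genes and the composition of its reads set PrP BMD5 replicate 3 apart from the other 29 libraries. Reads of rRNA made up 0.616% of this library, against at most 0.276% elsewhere. Its 10 most abundant genes held 27.7% of the reads, against at most 18.4% elsewhere. Of its reads 797296 fell on zgc:158463 and 771365 on CT027638.1, 7.93% of the library for the former. The RNase P RNA gene rpph1 stood at 13.7 CPM there against at most 4.20 CPM elsewhere.

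Transcripts and genes gave different values for ckbb, the brain-type creatine kinase. A transcript of it was higher by 1.22 ± 0.16 SE at MtP BMD5/50 (adjusted p = 0.00492) and by 1.12 ± 0.16 at EtP BMD5/50 (adjusted p = 0.0169). The sum of its 8 transcripts had 0.36 ± 0.18 and 0.09 ± 0.18.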
